A study of Mus musculus with 9 samples.

How the data were processed

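RNA from 3 mouse cell lines was measured on Affymetrix MG-430 2.0 arrays, 3 arrays per line and 9 in all. Per the labels, total RNA was purified on silica columns with a DNase step, checked by its ratio of ribosomal RNA bands and turned into biotin-labelled cRNA by in vitro transcription. The deposited values are log2 signals, 1 column per array and 1 value for each of 45101 probe sets. The authors' background correction, summarization and normalization are not given in the sources used here. The columns had been brought to nearly the same distribution before deposit, with array medians between 6.28 and 6.34. Arrays give no counts, so the number of arrays limits the precision.

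Probe sets were joined to genes through the platform's annotation as supplied. Of the probe sets, 64 were controls, 34945 carried exactly 1 gene symbol, 932 carried several and 9160 carried none. Of those with 1 symbol, 34741 were also matched to the gene table by Entrez ID. Each gene was represented by its single-symbol probe set with the highest mean over the 9 arrays, which left 18193 genes, and 9010 of these had several probe sets. Probe sets with several symbols or none were left out because their signal cannot be given to 1 gene.

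One linear model per gene was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes without an intensity trend, with statmod 1.5.0) in R 4.3.3, which left 6 residual degrees of freedom. The comparisons were knockout against wild-type line, tumour against knockout line, and tumour against wild-type line. A gene was called when its Benjamini-Hochberg adjusted p over the 18193 genes was under 0.05 and its difference was at least 2-fold. All limma p-values are two-sided. Values are given as the log2 difference with the standard error of limma's moderated fit, or as a mean with its SD over 3 arrays. Where all 3 arrays of the dimmer group lay under the 95th percentile of the 27 bacterial control probe sets, a log2 signal of 5.15, the fold was computed against that floor and is given as a lower bound; this floor was chosen after seeing the data. A log2 difference printed beside such a bound is a difference of signals and rests in part on background, and genes were ranked by these differences. A fold printed without a bound also rests in part on background where the dimmer group's mean lay close to or under the floor.

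The detection of known changes was tested on simulated data of the same size and spread. Of 50 genes planted at each fold in each comparison, the procedure called 0 at 1.5-fold. At 2.5-fold it called 49 for knockout against wild-type, 49 for tumour against knockout and 50 for tumour against wild-type. At 4-fold and 8-fold it called 50 in each comparison. It made 0 calls in the wrong direction and 0 among the unchanged genes.

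Before the data were examined, 35 gene lists were fixed, with 684 members of which 642 were measured; they hold 664 different genes, and 20 of these stand in more than 1 list. They cover signalling and stress responses, proliferation, metabolism, epithelial, airway and alveolar identity, and markers of other cell types. Each list was tested in each comparison with camera (limma) at a preset correlation of 0.01 between genes, and the 105 p-values were adjusted together by Benjamini-Hochberg. Camera asks whether a list's genes moved further up, or further down, than the other genes did. A list whose genes moved both ways can therefore miss the threshold. Camera was repeated with a correlation estimated per list. The fry test was also run; its one-direction p asks whether a list's genes move on balance one way and its mixed p whether they move in either direction, and neither compares the list with other genes.

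The named genes follow a rule fixed at the same time. It takes the Gprc5 family, the sex-linked genes and the control probe sets. It also takes, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose arrays do not overlap, without predicted or clone names and without cross-hybridising probe sets ending in _x_at. For each list described it takes up to 6 called members with the largest change, and for the overlaps the 10 genes per direction with the largest smaller change. Genes named outside this rule are said to have been chosen after their values were seen.

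RNA integrity was read from the 3' and 5' control probe sets of beta-actin and Gapdh as a log2 difference per array, compared between groups by an exact two-sided permutation test whose smallest p for 3 against 3 arrays is 0.1. Overlaps of calls were set beside the product of the 2 counts divided by the number of genes, and beside 50 simulations of unchanged groups that share the same control arrays.

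The alternatives tried were quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, every probe set on its own, no fold threshold, a 1.5-fold threshold, an intensity trend with a robust prior, fitting only the 6 arrays compared, the replicate number as a block, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.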

Results

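Gene expression was measured in 3 mouse lines. The wild-type line is a non-tumorigenic epithelial line grown from the trachea of a 3-week-old mouse with intact Gprc5a, and the knockout line is its counterpart from a Gprc5a-knockout mouse of the same age. The tumour line, MDA-F471, was grown from a lung adenocarcinoma of a female knockout mouse 16 months after the tobacco carcinogen NNK. Each line was measured on 3 arrays. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these arrays. With 1 line per group, the line, its handling batch and its genotype cannot be told apart. The sample titles number the tumour arrays apart from the others. The hybridisation control BioB-M read 7.60 to 8.24 log2 on the tumour arrays and 8.32 to 9.48 on the others. A further such control, CreX-3, overlapped, at 12.90 to 13.34 against 13.33 to 13.97. The tumour line also differs from both others in organ, NNK exposure and age of the mouse. These cannot be told apart from its tumour origin.

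Gprc5a, a retinoic acid-inducible receptor of airway epithelium that acts as a lung tumour suppressor, was lower in both knockout-derived lines. Its only probe set here (Entrez gene 232431) read 8.63, 8.74 and 8.32 log2 on the wild-type arrays (mean 8.57 ± 0.22 SD, n = 3). The knockout arrays read 7.20, 7.09 and 7.18 (7.16 ± 0.06 SD, n = 3) and the tumour arrays 6.96, 7.02 and 7.09 (7.02 ± 0.06 SD, n = 3). The log2 difference was -1.41 ± 0.11 for knockout against wild-type (limma adjusted p = 1.52e-07) and -1.54 ± 0.11 for tumour against wild-type (adjusted p = 1.25e-08). Between tumour and knockout it was -0.13 ± 0.11 (adjusted p = 0.370) and not called. Whether the probe set lies in the deleted part of the gene is unknown, so the remaining signal was not assigned to transcript or background. Gprc5b, Gprc5c and Gprc5d were not called in any comparison; Gprc5b, for example, differed by -0.32 between knockout and wild-type lines (adjusted p = 0.0225). With every probe set tested on its own, a second, dimmer Gprc5b probe set went the other way and stayed under 2-fold, by 0.16 there (adjusted p = 0.527), by 0.63 for tumour against knockout (adjusted p = 0.00259) and by 0.79 for tumour against wild-type (adjusted p = 0.000476). The Gprc5 family as a list had 1 of 4 members lower in both comparisons with the wild-type line, with adjusted p of 0.110 for knockout and 0.139 for tumour, and 0 called between tumour and knockout (adjusted p = 0.666).

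Arrays of 1 line resembled each other more than arrays of different lines. Across all probe sets but the controls, which are not independent replicates, Pearson's r lay between 0.990 and 0.996 within lines. Between knockout and wild-type arrays it lay between 0.971 and 0.975, between tumour and knockout arrays between 0.927 and 0.931, and between tumour and wild-type arrays between 0.913 and 0.920. The beta-actin 3' to 5' difference, a sign of RNA degradation or incomplete labelling, was 0.75, 1.09 and 1.78 on the wild-type arrays (1.21 ± 0.53 SD), against 0.93 ± 0.03 in the knockout and 0.57 ± 0.19 in the tumour line (n = 3 each). The difference was -0.28 for knockout against wild-type (exact permutation p = 0.6), -0.36 for tumour against knockout (exact p = 0.1) and -0.64 for tumour against wild-type (exact p = 0.1). For Gapdh the means were 0.81 ± 0.44, 0.52 ± 0.05 and 0.47 ± 0.27 in the wild-type, knockout and tumour lines. The Gapdh differences were -0.29, -0.05 and -0.34, with exact permutation p of 0.4, 0.7 and 0.3. Wild-type replicate 3 had the highest value of both controls, 1.78 for beta-actin and 1.2 for Gapdh.

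**Figure D1:**
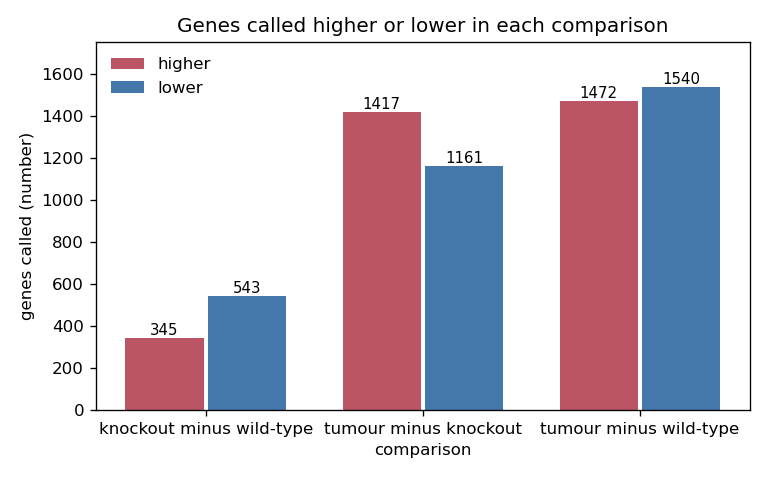
Number of genes called higher (red) or lower (blue) in each of the 3 comparisons, out of 18193 tested. Knockout against wild-type gave 345 higher and 543 lower, tumour against knockout 1417 and 1161, and tumour against wild-type 1472 and 1540.

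The comparison of knockout and wild-type lines asks what accompanies the loss of Gprc5a in non-tumorigenic airway cells. The neutrophil-attracting chemokine Cxcl5 was 45.2-fold higher in the knockout line (log2 difference 5.50 ± 0.23 SE, n = 3 arrays each), and Lcn2, which binds bacterial iron carriers, was 37.8-fold higher (5.24 ± 0.22). Ctsz, a lysosomal cysteine protease, was at least 28.0-fold higher (signal difference 6.70 ± 0.11) and Aldh1a1, which makes retinoic acid, was 20.9-fold higher (4.38 ± 0.16). Igfbp2, a binding protein of insulin-like growth factors, was 164-fold lower, from a mean of 12.59 to 5.23. Krtdap, a protein of differentiating keratinocytes, was 61.3-fold lower, and Lce3a, of the cornified envelope, was 38.0-fold lower. The other largest rises were Sncg at 5.0 and Tceal8 at 4.58 log2 and, from a background-level wild-type signal, Tmem47 (at least 18.1-fold), Akr1c13 (at least 16.8-fold), Zfp979 (at least 6.08-fold) and Hoatz (at least 5.27-fold). The other largest falls were Dapl1 at -5.59, H60c at -5.35 and Capns2 at -5.33 log2 and, to a background-level signal, Efemp1 (at least 43.6-fold), Sostdc1 (at least 33.2-fold), the Y-linked Eif2s3y (at least 14.4-fold) and C1qtnf3 (at least 11.7-fold). Among these 20 genes the largest limma adjusted p was that of Lcn2, 2.42e-10.

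In total 888 of 18193 genes were called (4.88%), 345 higher and 543 lower in the knockout line, and 231 of them differed at least 4-fold. The arrays of both lines did not overlap for 886 of the 888, and for 7111 of all genes, where chance gives 10%. The median log2 difference of all genes was -0.0042. Of the 478 called genes with several probe sets, 248 had another probe set called the same way and 0 had one called the opposite way.

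Targets of the transcription factor p53, which act in growth arrest, DNA repair and apoptosis, were higher as a group in the knockout line: 10 of 22 measured members rose, 1 fell and 11 were not called. Eda2r rose by 3.18 ± 0.14 log2, Zmat3 by 2.73 ± 0.10, Ccng1 by 2.15 ± 0.10 and the cell-cycle inhibitor Cdkn1a by 1.49 ± 0.10. Gadd45a fell by 1.16 log2. The list's median was 0.78 (camera adjusted p = 2.99e-09; adjusted p = 0.0628 with an estimated correlation). Interferon-stimulated genes, which block virus replication, were lower, with 0 of 26 rising and 6 falling. The log2 differences were -2.39 ± 0.21 for Ifit1 and -1.72 ± 0.11 for Usp18, and Oasl2 was at least 3.63-fold lower. The median was -0.39 (adjusted p = 5.06e-07; adjusted p = 0.189 with an estimated correlation). NF-kB targets had 6 members higher and 3 lower of 29, with Cxcl5 and Lcn2 above, the macrophage growth factor Csf1 at 2.27 ± 0.11 and the adhesion molecule Icam1 at -1.82 ± 0.10; the median was 0.20 (adjusted p = 0.0109; adjusted p = 0.40 with an estimated correlation).

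Genes of glycolysis and the hypoxia response were lower in the knockout line, with 5 of 25 falling and 0 rising: hexokinase Hk2 by -1.97 ± 0.14, Bnip3 by -1.50 ± 0.14, Aldoc by -1.32 ± 0.12, Ndrg1 by -1.29 ± 0.10 and the glucose transporter Slc2a1 by -1.18 ± 0.11 log2. Their median was -0.27 (adjusted p = 0.00152; adjusted p = 0.433 with an estimated correlation), and -0.16 with the mean of a gene's probe sets. Cell-cycle genes had 3 of 37 lower and 0 higher, namely Rrm2 at -1.56 ± 0.12, Mcm5 at -1.16 ± 0.13 and Cdc6 at -1.07 ± 0.10, all of DNA replication. Their median was -0.251 (camera adjusted p = 0.0172, and 0.573 with an estimated correlation). Without knockout replicate 2 the camera adjusted p was 0.0835, with a median of -0.255. With the mean of a gene's probe sets the median was -0.16 and the call of Mcm5 was lost (-0.79). The sex-linked list had 2 of 5 members lower, Eif2s3y and Uty (-1.08 ± 0.16), with a median of -0.33 (adjusted p = 0.0120; adjusted p = 0.232 with an estimated correlation); with the mean of a gene's probe sets 3 were lower and the median was -1.0. Uty was no longer called without wild-type replicate 2 (-0.87) or without knockout replicate 2 (-0.99).

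Eif2s3y, carried by the Y chromosome, read 9.0 ± 0.12 SD log2 in the wild-type line, 3.35 ± 0.06 in the knockout line and 3.32 ± 0.12 in the tumour line (n = 3 each). With every probe set tested on its own, Kdm5d, also on the Y chromosome, was not called between knockout and wild-type lines by its brightest probe set (-0.21, adjusted p = 0.142) or by a second (-0.23, adjusted p = 0.374). Another Kdm5d probe set, picked after its values were seen, read 8.25 ± 0.27, 3.67 ± 0.21 and 3.57 ± 0.06 in the same order of lines. A second Uty probe set, picked after its values were seen, read 7.87 ± 0.32, 5.42 ± 0.09 and 3.26 ± 0.21. It was lower in the tumour than in the knockout line (limma adjusted p = 4.10e-07). The knockout value of 5.42 lay above the floor of 5.15 but under the highest bacterial control value, 5.96. The brightest Kdm5d probe set read 5.23 even in the tumour line, from a female mouse. The Uty signal of the knockout line was therefore not assigned to transcript or background. Xist, the RNA that silences 1 X chromosome in female cells, read 7.58 ± 0.27, 7.25 ± 0.19 and 11.22 ± 0.42 on its brightest probe set. Another Xist probe set read 4.51, 4.12 and 9.12 in the same order of lines, and a further one 4.24, 4.66 and 6.51. Both lay under the floor of 5.15 in the wild-type and knockout lines. On the brightest probe set Xist rose by 3.98 ± 0.18 log2 in the tumour against the knockout line (limma adjusted p = 1.42e-10). The sex-linked list was not past its threshold there (1 higher, 0 lower of 5, adjusted p = 0.647) or for tumour against wild-type (1 higher, 2 lower, adjusted p = 0.425).

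Krt5 and Krt14 mark airway basal cells, the stem cells of this epithelium, and had a high signal in both tracheal lines. Krt5 read 14.46 in the wild-type and 14.38 in the knockout line (log2 difference -0.07, not called), and Krt14 14.52 and 14.68 (0.16, not called). Of the basal cell markers, 3 of 18 were lower in the knockout line, the desmosomal cadherin Dsc3 (-2.52 ± 0.12), the water channel Aqp3 (-1.51 ± 0.14) and the basal-cell factor Trp63 (-1.36 ± 0.12), with adjusted p = 0.10 for the list; the call of Trp63 was lost with the mean of its probe sets (-0.67). Markers of other cell types had few calls in this comparison. Fibroblast markers had 0 higher and 1 lower of 19 (adjusted p = 0.820), smooth muscle markers 0 and 2 of 10 (0.440; Acta2 was not called with the mean of its probe sets, -0.50, or without those ending in _x_at or _s_at, -0.13), and cartilage (0.476), ciliated (0.115), leukocyte (0.439) and endothelial (0.548) markers 0 called.

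**Figure D2:**
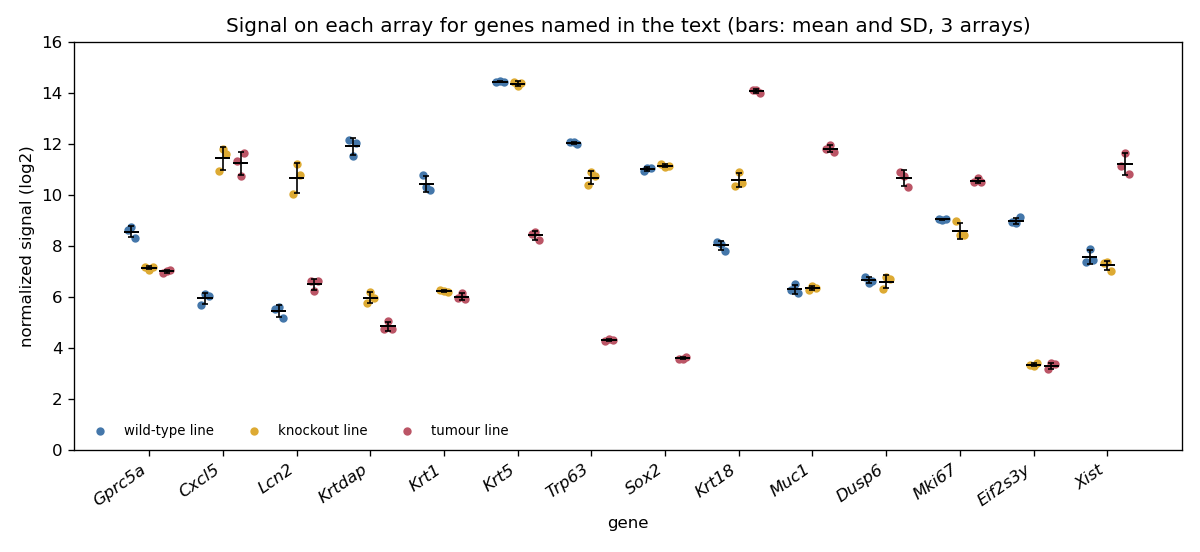
Normalized log2 signal of 14 genes on each of the 9 arrays, coloured by line; each point is 1 array, and the bars give the mean and SD of 3 arrays. Gprc5a, Krtdap, Krt1 and Eif2s3y were higher in the wild-type line than in both others, Krt5, Trp63 and Sox2 were lowest and Krt18, Muc1 and Dusp6 highest in the tumour line; Krt1 and Mki67 were picked after their values were seen.

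The comparison of tumour and knockout lines sets an adenocarcinoma line against a non-tumorigenic line of the same genotype. The organ, the NNK exposure and the age of the mouse differ as well. Krt17, a keratin of basal and activated epithelial cells, was at least 216-fold lower in the tumour line (log2 difference -9.11 ± 0.10 SE, n = 3 arrays each), and Col17a1, which anchors basal cells to the basement membrane, at least 447-fold lower (-9.03 ± 0.10). Sox2, a factor that keeps airway stem cells, was at least 64.7-fold lower (-7.56 ± 0.09). Krt19, a keratin of simple epithelia, was 107-fold higher, at 12.05 in the tumour and 5.32 in the knockout line, while the wild-type line read 10.22. Ctla2a, an inhibitor of cathepsins, read 228-fold higher (7.83 ± 0.10), and Ccn2, a matrix-associated growth factor, was 164-fold higher (7.36 ± 0.20). The knockout mean of Ctla2a, 5.14, lay just under the floor of 5.15, so its fold rests in part on background.

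The other largest rises were Ankrd1 at 6.49, the thrombin receptor F2r at 6.48, Igfbp7 at 6.05 and Dusp4 at 5.89 log2. Those from a background-level signal were Ctla2b (at least 81.8-fold), the actin-bundling Lcp1 (at least 57.7-fold) and the chemokine Cxcl3 (at least 21-fold). The knockout mean of Ankrd1, 4.95, also lay under the floor of 5.15, so its difference rests in part on background. The other largest falls were Ifitm3 at -8.05, Dmkn at -7.45, Krt6b at -7.37 and Cbr2 at -7.04 log2 and, to a background-level signal, Krt13 (at least 105-fold), Spink5 (at least 87.2-fold) and the apoptosis inducer Pmaip1 (at least 42.8-fold). Of 18193 genes 2578 were called (14.2%), 1417 higher and 1161 lower, and 821 differed at least 4-fold. The arrays of the 2578 called genes did not overlap, nor did those of 9520 of all genes, where chance gives 10%. The median of all genes was 2.7e-05. Of the 1531 called genes with several probe sets, 857 had another called the same way and 4 another called the opposite way, none of them named here.

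Cell-cycle genes were higher as a group in the tumour line: 34 of 37 measured members rose and 0 fell. The replication licensing factor Cdc6 rose by 4.49 ± 0.10 log2, the mitotic checkpoint kinase Bub1 by 3.13 ± 0.13, Rrm2, which makes deoxynucleotides, by 3.06 ± 0.12 and the mitotic kinesin Kif23 by 2.99 ± 0.09. The median was 2.20 (camera adjusted p = 7.05e-23; adjusted p = 0.184 with an estimated correlation). Output genes of the Ras and MAPK pathway, many of them feedback inhibitors, had 13 of 19 members higher and 1 lower. The phosphatases Dusp4 and Dusp6 rose by 5.89 ± 0.14 and 4.07 ± 0.15 log2, the inhibitor Spry2 by 3.30 ± 0.20 and the urokinase receptor Plaur by 2.99 ± 0.22, while the early transcription factor Egr1 fell by 2.29. The median was 2.27 (adjusted p = 2.39e-07; adjusted p = 0.223 with an estimated correlation).

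Airway basal cell markers were lower, with 13 of 18 falling and 0 rising. Beside Krt17 and Col17a1, the log2 differences were -7.42 ± 0.10 for Krt14, -6.45 ± 0.10 for Krt15 and -5.96 ± 0.10 for Krt5, and Trp63 was at least 46.5-fold lower. Their median was -5.12 (adjusted p = 6.60e-15), and this call held with an estimated correlation (adjusted p = 0.0257); with the mean of a gene's probe sets the median was -2.75. Airway secretory cell markers had 5 lower and 1 higher of 20, among them the carbonyl reductase Cbr2, Krt13 and the cytochrome Cyp2f2 (-5.55 ± 0.22), and missed the threshold (median -0.17, adjusted p = 0.0847); the list passed it without knockout replicate 1 (adjusted p = 0.0359), without the dimmest 40% of probe sets (0.0326) and without probe sets ending in _x_at or _s_at (0.0464). Its adjusted p over 18 alternatives ranged from 9.10e-06 by fry to 0.433 with an estimated correlation.

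Alveolar type II and lung lineage markers had 6 higher and 1 lower of 19, and as a list missed the threshold (median 0.19, adjusted p = 0.10). The mucin Muc1 rose by 5.47 ± 0.11 log2, the transcription factor Foxa1 by 2.62 ± 0.09 and Lpcat1, of surfactant lipid synthesis, by 2.61 ± 0.12, while Cebpa fell by 3.40. The surfactant gene Sftpc (-0.02) and the lung lineage factor Nkx2-1 (-0.12) were not called. Genes of epithelial adhesion and junctions went both ways, 7 higher and 5 lower of 29 (median 0.31, adjusted p = 0.439). Krt19, the claudins Cldn7 (4.58 ± 0.11) and Cldn3 (4.02 ± 0.14) and Krt18 (3.50 ± 0.13) rose, and the desmosomal Dsp fell by 2.66. Mesenchymal transition genes had 1 higher and 4 lower of 19 (median -0.22, adjusted p = 0.133), with the repressor Snai2 at -4.92 ± 0.09. Cyclin-dependent kinase inhibitors and the Rb family had 2 higher and 5 lower of 15 (median -0.39, adjusted p = 0.10), with cyclin Ccnd2 at -4.93 ± 0.15, the inhibitors Cdkn2b at -3.74 ± 0.13 and Cdkn2a at -1.71 ± 0.13, and cyclin Ccnd1 at 1.28 ± 0.12.

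The NF-kB, interferon, p53 and glycolysis lists, each past the threshold in a comparison with the wild-type line, missed it between tumour and knockout lines; the difference between comparisons was not tested. NF-kB targets had 10 higher and 2 lower of 29 (median 0.15, adjusted p = 0.139), with Tnfaip2 at 3.19 ± 0.10 and Lcn2 at -4.19 ± 0.22. Interferon-stimulated genes had 3 higher and 7 lower of 26 (median -0.22, adjusted p = 0.10), with Usp18 at 3.31 ± 0.11 and Gbp2 at -3.07 ± 0.11. The p53 targets had 2 higher and 5 lower of 22 (median -0.30, adjusted p = 0.115), with Pmaip1 lowest and Gadd45a at 2.10 ± 0.13. Glycolysis and hypoxia genes had 2 higher and 4 lower of 25 (median 0.14, adjusted p = 0.451), with Hk2 at 3.41 ± 0.14. Ras and MAPK output genes had 1 higher and 2 lower of 19 between knockout and wild-type lines (median 0.08, mean -0.01, camera direction up, adjusted p = 0.750).

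Among markers of other cell types, 3 of 16 leukocyte genes were higher in the tumour line, Lcp1, the endotoxin co-receptor Cd14 (3.06 ± 0.12) and Cd53 (1.53 ± 0.15), while the pan-leukocyte gene Ptprc differed by 0.07 and was not called. The leukocyte list was not past the threshold (adjusted p = 0.314), and the call of Cd53 was lost with the mean of its probe sets (0.74). Endothelial (0 of 14, adjusted p = 0.869) and fibroblast markers (0 of 19, 0.869) had no calls. Ciliated cell markers had 2 higher of 19, Tubb4b (1.56 ± 0.09) and Ift57 (1.01 ± 0.11), and both calls were lost with the mean of their probe sets (0.34 and 0.49). Ift57 was also no longer called under quantile normalization (0.94) or without knockout replicate 1 (0.95), tumour replicate 2 (0.96) or tumour replicate 3 (0.96). The ciliated list's median was -0.03, the mean 0.03 and the camera direction down (adjusted p = 0.869). Smooth muscle markers had Mylk higher (3.77 ± 0.14) and Acta2 lower (-1.61 ± 0.10) of 10, with a median of -0.0065, a mean of 0.22 and camera direction up (adjusted p = 0.983); Acta2 differed by -0.58 with the mean of its probe sets and by 0.03 without those ending in _x_at or _s_at, and was called in neither. Cartilage markers had Sox9 lower (-1.94 ± 0.12) of 13, with a median of 0.07, a mean of -0.03 and camera direction up (adjusted p = 0.849).

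**Figure D3:**
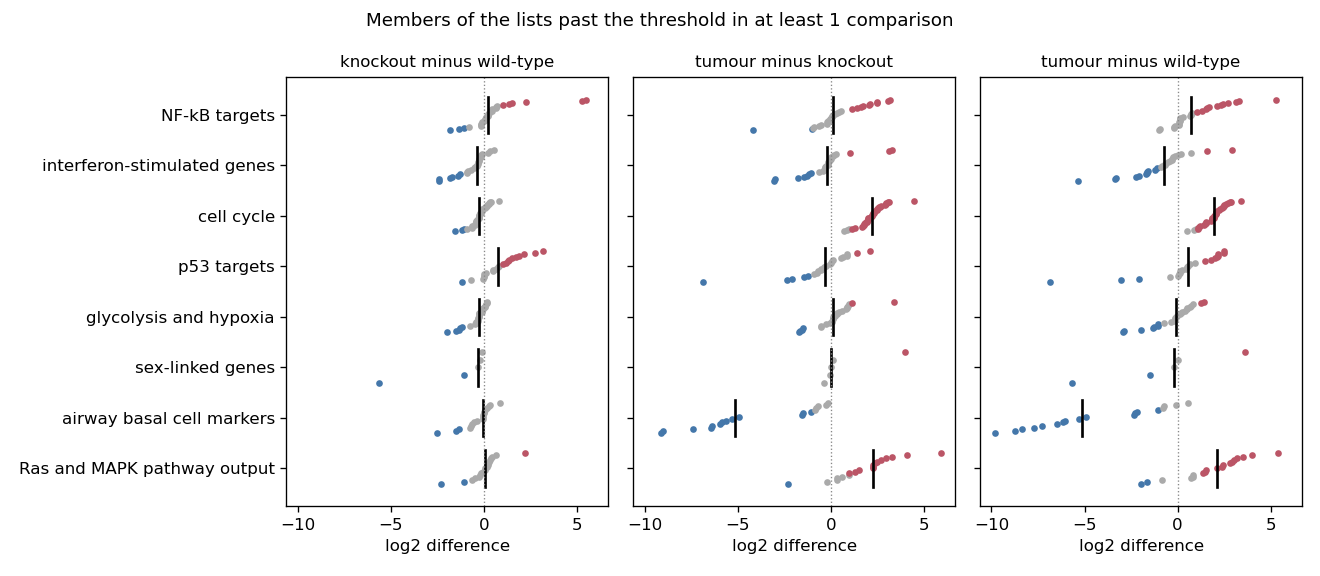
Log2 differences of the members of the 8 lists past the threshold in at least 1 comparison, 1 panel per comparison; each point is a gene (red called higher, blue called lower, grey not called) and the black line is the list's median. Cell-cycle medians were 2.20 and 1.98 in the tumour line against knockout and wild-type, and basal cell marker medians -5.12 in both.

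Between tumour and wild-type lines the genotype, the tumour origin, the organ, the NNK exposure and the age of the mouse all differ. Krt18, a keratin of simple epithelia, was 66.3-fold higher in the tumour line (log2 difference 6.05 ± 0.13 SE, n = 3 arrays each) and the tight-junction claudin Cldn7 was 104-fold higher (6.70 ± 0.11). Trp63, the master factor of basal and squamous epithelia, was at least 120-fold lower (-7.73 ± 0.12), and Dsc3, of the desmosomes, at least 132-fold lower (-8.36 ± 0.12). The other largest rises were Ccn2 at 6.94 log2 and, from a background-level signal, Ctla2a (at least 226-fold), Ctla2b (at least 81.8-fold), Ankrd1 (at least 78.3-fold), Lcp1 (at least 57.7-fold), Bcl2l15 (at least 53-fold), Ctsz (at least 27.2-fold) and Cxcl3 (at least 21-fold). The other largest falls were Dmkn at -8.01 and Krt6b at -7.97 log2 and, to a background-level signal, Col17a1 (at least 366-fold), Krt17 (at least 354-fold), Krt16 (at least 248-fold), Spink5 (at least 217-fold), Krt13 (at least 199-fold) and Sox2 (at least 59.3-fold).

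Of 18193 genes 3012 were called (16.6%), 1472 higher and 1540 lower, and 978 differed at least 4-fold. The arrays did not overlap for 3011 of them and for 9960 of all genes, where chance gives 10%. The median of all genes was 0.01. Of the 1787 called genes with several probe sets, 1022 had another called the same way and 3 another called the opposite way, none of them named here.

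Cell-cycle genes had 34 of 37 members higher and 0 lower than in the wild-type line, with Cdc6 at 3.41 ± 0.10, Kif23 at 2.86 ± 0.09 and the ubiquitin enzyme Ube2c at 2.82 ± 0.15 log2. The median was 1.98 (adjusted p = 6.70e-20; adjusted p = 0.189 with an estimated correlation). Basal cell markers had 14 of 18 lower and 0 higher, with a median of -5.12 (adjusted p = 2.37e-13), and this call too held with an estimated correlation (adjusted p = 0.0257). With the mean of a gene's probe sets the median was -3.24. Ras and MAPK output genes had 13 higher and 2 lower of 19, with Dusp4 at 5.41 ± 0.14, Dusp6 at 4.02 ± 0.15, Ccnd1 at 3.49 ± 0.12 and Plaur at 3.19 ± 0.22. The median was 2.11 (adjusted p = 6.75e-06; adjusted p = 0.256 with an estimated correlation).

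NF-kB targets had 12 of 29 members higher than in the wild-type line and 0 lower: Cxcl5 rose by 5.29 ± 0.23 log2, the colony-stimulating factor Csf2 by 3.27 ± 0.10, the pathway inhibitor Tnfaip3 by 3.16 ± 0.09 and Csf1 by 2.72 ± 0.11. Their median was 0.71 (adjusted p = 0.000504; adjusted p = 0.256 with an estimated correlation). Interferon-stimulated genes had 11 lower and 2 higher of 26, with Gbp2 at -3.35 ± 0.11, Ifit1 at least 30.7-fold lower and the antiviral Mx1 at least 3.97-fold higher. Their median was -0.76 (adjusted p = 0.000116; adjusted p = 0.256 with an estimated correlation). The p53 targets had 8 higher and 3 lower of 22, with Eda2r at 2.51 ± 0.14, Zmat3 at 2.48 ± 0.10 and Plk2 at 2.18 ± 0.19, against Sesn1 at -3.02 ± 0.12 and the apoptosis inducer Pmaip1, at least 42.2-fold lower. Their median was 0.54 (adjusted p = 0.0347; adjusted p = 0.40 with an estimated correlation). This p53 call was lost without wild-type replicate 3, the array with the highest 3' to 5' differences (median 0.47, camera adjusted p = 0.0540). It was also lost without the dimmest 40% of probe sets (median 0.54, camera adjusted p = 0.0664). The medians thus changed little, and the cause of the losses was not tested.

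Apart from the basal cell markers, the lists of lineage and of other cell types were not past the threshold for tumour against wild-type. Alveolar type II and lung lineage markers had 5 higher and 1 lower of 19 (median 0.17, adjusted p = 0.0847; 0.0254 and past the threshold with the mean of probe sets, from 5.94e-06 by fry to 0.40 with an estimated correlation over 18 alternatives), with Muc1 at 5.52 ± 0.11 and the surfactant protein Sftpd at 1.81 ± 0.11. Alveolar type I markers had 3 higher and 3 lower of 12, with Igfbp2 at -7.36 ± 0.13 and the membrane glycoprotein Pdpn at -3.83 ± 0.10; the median was 0.01, the mean -0.79 and the camera direction down (adjusted p = 0.597). Airway secretory markers had 2 higher and 4 lower of 20, with a median of 0.01, a mean of -0.90 and camera direction down (adjusted p = 0.522). Epithelial junction genes had 9 higher and 7 lower of 29 (median 0.45, adjusted p = 0.405), mesenchymal transition genes 1 and 6 of 19 (-0.16, 0.123), and the cyclin-dependent kinase inhibitors and Rb family 1 and 4 of 15 (-0.47, 0.10). Glycolysis and hypoxia genes had 2 higher and 7 lower of 25 (median -0.08, adjusted p = 0.597), with Ndrg1 at -2.96 ± 0.10. Leukocyte markers had 3 higher of 16 (0.08, 0.220), gastrointestinal and gut markers 3 higher of 15 (0.08, 0.180), ciliated markers 2 higher of 19 (0.03, 0.567), and endothelial markers 0 of 14 (0.05, 0.849). With the mean of probe sets the ciliated calls, Tubb4b (0.46) and Ift57 (0.53), were lost, as were those of the leukocyte gene Cd53 (0.92) and the cartilage gene Sox9 (-0.83); Acta2 was not called without probe sets ending in _x_at or _s_at (-0.11). Fibroblast markers had 0 of 19 called (median 0.01, mean -0.06, camera direction down, adjusted p = 0.849), smooth muscle markers 1 higher and 2 lower of 10 (0.08, -0.05, down, 0.898), and cartilage markers 1 lower of 13 (median 0.12, adjusted p = 0.630).

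The alveolar, secretory, junction, mesenchymal, cyclin-dependent kinase inhibitor and gut lists also missed the threshold in the other comparisons. Alveolar type II markers had 1 higher (Cebpa, 1.15 ± 0.12) and 1 lower (Foxa1, -1.95 ± 0.09) in the knockout against the wild-type line, with a median of -0.0029 and camera direction up (adjusted p = 0.597). Alveolar type I markers had Igfbp2 and Pdpn (-3.72 ± 0.10) lower there (median -0.22, adjusted p = 0.0957), and 3 higher and 1 lower in tumour against knockout (0.02, 0.811). Airway secretory markers had Ltf, an iron-binding secreted protein, higher (3.29 ± 0.23) and Krt4 lower (-2.19 ± 0.18) in the knockout line (median 0.15, adjusted p = 0.141). Epithelial junction genes had Krt18 (2.55 ± 0.13) and Cldn7 (2.12 ± 0.11) higher and Krt19 (-4.90 ± 0.13) and Ovol1 (-1.26 ± 0.09) lower there, with a median of -0.0025, a mean of -0.03 and camera direction up (adjusted p = 0.868); the call of Ovol1 was lost with the mean of its probe sets (-0.85). Mesenchymal transition genes had 1 higher and 3 lower (-0.08, adjusted p = 0.526) and the cyclin-dependent kinase inhibitors 2 and 2 (-0.24, 0.522), with Cdkn2a at -1.96 ± 0.13. The call of Cdkn1c, also lower, was lost without wild-type replicate 1 (-0.94) and without knockout replicate 1 (-0.90). Gastrointestinal and gut markers had 1 higher of 15 in the knockout line, Ctse (1.43 ± 0.28, adjusted p of the list 0.522), which was not called with the mean of its probe sets (0.66) or without those ending in _x_at or _s_at (-0.11). In tumour against knockout 2 gut markers were higher, the actin-bundling Vil1 (1.44 ± 0.11) and Cdh17 (1.09 ± 0.11; list adjusted p = 0.306).

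In these list counts, the number of called members adjusted over the list alone equalled the number adjusted over all genes in each of the 105 tests. With an estimated correlation only the basal cell marker lists in the comparisons with the tumour line stayed past the threshold. By fry's one-direction p after Benjamini-Hochberg adjustment, 24 lists were past 0.05 for knockout against wild-type, 26 for tumour against knockout and 29 for tumour against wild-type. Other splits of the 6 arrays of a comparison gave up to 5, 6 and 4 lists past the threshold, where the real splits gave 6, 4 and 6 in the same setting, so the number of lists alone does not set a comparison apart.

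Of the genes called in the knockout line against wild-type, 529 were called in the same direction in the tumour line against wild-type, 144 higher and 385 lower. Cxcl5 was higher by 5.50 and 5.29 log2 in knockout and tumour lines and the aldehyde dehydrogenase Aldh2 by 3.42 and 4.02, Ctsz at least 28.0-fold and at least 27.2-fold, and Akr1c13 at least 16.8-fold and at least 31.2-fold. Igfbp2 was lower by -7.36 and -7.36 log2, Lce3a by -5.25 and -5.50, Krtdap 61.3-fold and at least 109-fold, and the matrix protein Efemp1 at least 43.6-fold in both. The counts expected for independent calls were 27.9 higher and 46.0 lower. In opposite directions stood 38 genes higher in the knockout and lower in the tumour line (expected 29.2) and 31 the reverse (expected 43.9). The wild-type arrays serve both comparisons and cannot be split so that each part keeps 2 arrays, so part of the excess may come from them. Across genes the differences had r = 0.43 where shared controls alone gave 0.50 in simulation. The covariance was 0.227 against a simulated 0.00755, so the spread of the shared arrays alone gave little of it. The simulation held only that spread. Whatever is particular to the single wild-type line enters both comparisons with the same sign, as the Y-linked Eif2s3y did (-5.65 and -5.68). How much of the overlap comes from this was not tested. The 50 simulations gave 0 shared calls, but they held no changed genes and were bound to give almost none. That 0 therefore says nothing about the overlap.

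Fewer genes moved stepwise: 151 were called in the same direction from wild-type to knockout and again from knockout to tumour line, 36 higher and 115 lower (expected 26.9 and 34.7). Krt18 rose by 2.55 and then 3.50 log2, Cldn7 by 2.12 and 4.58, and Rdh10, which oxidises retinol, by 1.87 and 2.28. The first falls were -2.52 log2 for Dsc3, -3.81 for the epidermal protein Rptn, -4.13 for the desmoglein Dsg1b and -2.39 for Ifit1. The second ended at background level and was at least 22.9-fold for Dsc3, 5.94-fold for Rptn, 1.76-fold for Dsg1b and 5.85-fold for Ifit1. In the opposite direction, 146 genes were higher in the knockout line and lower again in the tumour line (expected 22.0), and 88 were lower and then higher (expected 42.3). The knockout arrays serve both steps with opposite sign. Across genes r was -0.11 against a simulated -0.50, and the covariance was -0.0528 against -0.00751. Here too the simulation held only the spread between arrays, and what is particular to the knockout line was not separated.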

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

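No test in this part was chosen after its result was seen, and no explanation was tested for these values. Signal appeared in data that the comparisons above do not use. Among the 9160 probe sets that carry no gene symbol, 114 were called in the knockout against the wild-type line, 52 higher and 62 lower. In the tumour against the knockout line 339 of them were called, 132 higher and 207 lower. In the tumour against the wild-type line 377 were called, 149 higher and 228 lower. The array's control probe sets for the mouse transferrin receptor, the iron-uptake receptor, gave a higher signal in the tumour than in the wild-type line, by a mean of 3.38 log2 over 3 sets. This mean is no measure of transcript, since the middle and 5' sets read under the floor of 5.15 in the wild-type line; against the floor they were at least 6.26-fold and 3.15-fold higher, and the 3' set was 11.9-fold higher. The 3' set read 5.40 ± 0.19 SD in the wild-type, 5.78 ± 0.09 in the knockout and 8.98 ± 0.54 in the tumour line (n = 3 each), the middle set 4.33 ± 0.08, 4.58 ± 0.16 and 7.80 ± 1.13, and the 5' set 3.72 ± 0.11, 3.88 ± 0.14 and 6.80 ± 0.85.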

How the results depend on the processing

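The alternatives were fixed before the data were examined, except the floor for folds, which was chosen after seeing the data. Of 1901 gene results with 37657 alternative values, 171 values were no longer called, 919 became called and 5 changed sign. Most of the 919 came by construction from looser thresholds, 511 without a fold threshold and 253 at 1.5-fold. The tumour and wild-type difference of Hoxa5 turned to -1.06 with the mean of its probe sets and to -2.13 without probe sets ending in _x_at or _s_at. The latter setting also turned Ctse in knockout against wild-type to -0.11, Acta2 in tumour against knockout to 0.028 and Dlk1 in tumour against wild-type to 0.24. By fry the Wnt list moved down in tumour against knockout, where camera gave up and the median is 0.039. The cause was not tested for these changes.

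The numbers of called genes for knockout against wild-type, tumour against knockout and tumour against wild-type, of shared genes and of stepwise genes grew by construction in 3 settings. They were 1672, 5119, 5908, 970 and 259 with every probe set on its own, 4805, 8103, 8614, 2820 and 1370 without a fold threshold, and 2178, 4881, 5386, 1263 and 481 at 1.5-fold. Both scalings, the dim filter, the other choices of probe set, the trend and robust prior, the 6-array fit and the replicate block kept these counts within 1.5 times. Lists past the threshold in tumour against knockout became 5 with the mean of probe sets and 6 without those ending in _x_at or _s_at. With an estimated correlation 0, 1 and 1 lists were past the threshold, and by fry's adjusted p 24, 26 and 29; fry asks another question, and the cause of the other changes was not tested. The share of calls that are higher moved from 38.9% to 42.6% for knockout against wild-type and from 55.0% to 51.4% for tumour against knockout under quantile normalization.

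Leaving out each array in turn gave 885 to 904, 2552 to 2637 and 2993 to 3082 called genes, 523 to 531 shared and 146 to 154 stepwise genes. Gprc5a differed by -1.53 to -1.32, -0.17 to -0.10 and -1.66 to -1.45. Lists past the threshold ranged from 5 (without knockout replicate 2) to 6, from 3 to 6 (without knockout replicate 1), and from 5 (without wild-type replicate 3) to 6. The beta-actin 3' to 5' difference ranged from -0.51 to 0.0065 (without wild-type replicate 3), from -0.44 to -0.26 and from -0.87 to -0.35, and that of Gapdh from -0.53 to -0.097, from -0.19 to 0.075 (without tumour replicate 1) and from -0.58 to -0.15.

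No clear pairing of the arrays by replicate number was seen, though 3 arrays per line are too few to exclude it. The 9 pairs with the same number in different lines had residual r from -0.145 to 0.278 across probe sets (median 0.047). The 18 pairs with different numbers had r from -0.214 to 0.239 (median -0.037), and 3 of 9 arrays matched best with their own number. With the number as a block 888, 2578 and 3012 genes and 6, 4 and 6 lists were called, the TGF-beta and YAP list joining in tumour against knockout. A pseudocount does not apply to log2 values, and the sex-linked list gives no value under the dim filter. Signal near the bacterial controls, whose 95th percentile is 5.15 log2, limits the folds of dim genes. They are lower bounds only where all 3 arrays of the dimmer group lay under that percentile.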

Other observations

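The tests of RNA quality in the p53 targets, of swapped arrays and the share of sex-chromosome genes, of circular shifts and gene shuffles along the chromosomes, of the neighbours of Gprc5a and of symbol families were chosen only after the results were seen; the other tests here were planned. Genes of detoxification and retinoid handling differed between the lines without a uniform direction; the genes named here and in the next 2 paragraphs were picked from their lists after their values were seen. Targets of NRF2, the factor of the antioxidant response, had 5 higher and 4 lower of 24 in the knockout against the wild-type line (camera adjusted p = 0.140), with the glutathione transferase Gsta3 at 2.36 ± 0.12 log2 and the peroxidase Gpx2 at -3.08 ± 0.10. In tumour against knockout 6 were higher and 7 lower (median 0.31, mean -0.0063, camera direction up, adjusted p = 0.662), with Gsta3 at -4.28 ± 0.12 and the thioredoxin reductase Txnrd1 at 2.42 ± 0.09; in tumour against wild-type 5 were higher and 7 lower (adjusted p = 0.798). Retinoid genes had 2 of 20 higher in the knockout line, Aldh1a1 (4.38 ± 0.16) and Rdh10 (1.87 ± 0.16; list adjusted p = 0.136). In tumour against knockout 3 were higher and 3 lower (0.898), with the retinoic acid binding protein Crabp2 at -5.69 ± 0.09, and in tumour against wild-type 6 were higher and 2 lower (0.439). The aryl hydrocarbon receptor and NNK-metabolising genes had 2 of 15 higher in the knockout line, Aldh3a1 (1.96 ± 0.14) and the DNA repair enzyme Mgmt (1.64 ± 0.10; list adjusted p = 0.468). In tumour against knockout 2 were higher and 3 lower (0.0600), with the NNK-activating airway cytochrome Cyp2f2 at -5.55 ± 0.22 and Aldh3a1 at -3.94 ± 0.14; in tumour against wild-type 3 were higher and 5 lower (0.297). The tumour against knockout list passed its threshold with the mean of probe sets (0.0488), without probe sets ending in _x_at or _s_at (0.0493) and without knockout replicate 1 (0.0372), and ranged over 18 alternatives from 0.000141 by fry to 0.445 with an estimated correlation.

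Signalling lists outside the report's account also went both ways. Targets of TGF-beta and YAP had 1 higher and 5 lower of 18 in the knockout line (adjusted p = 0.297), with the inhibitors of differentiation Id3 at -3.66 ± 0.14 and Id2 at -3.21 ± 0.13. In the tumour against the knockout line 7 were higher and 1 lower (median 0.66, camera adjusted p = 0.0556). Ccn2 differed by 7.36 ± 0.20, Ankrd1 by 6.49 ± 0.11 from a knockout mean under the floor, and Tgfbi was at least 41.2-fold lower. Against the wild-type line 6 were higher and 3 lower (camera adjusted p = 0.167). Against the knockout line the list lay near its threshold and passed it in 10 of 18 alternatives. These were the replicate block (0.0297), the 6-array fit (0.0344), the mean of probe sets (0.0438), no probe sets ending in _x_at or _s_at (0.0373), fry (4.10e-05), and leaving out wild-type replicate 1 (0.0353) or 2 (0.0462), knockout replicate 1 (0.0276), or tumour replicate 2 (0.0490) or 3 (0.0444); the highest adjusted p was 0.445, with an estimated correlation. Wnt targets and antagonists had 1 higher and 3 lower of 23 in the knockout line (0.10), 2 and 3 in tumour against knockout (median 0.04, mean -0.12, camera direction up, 0.849) and 3 and 2 in tumour against wild-type (0.350), with the ligand Wnt4 at -1.60, -3.29 and -4.89 log2. In the knockout line the Wnt list passed the threshold with the mean of probe sets (median -0.17, adjusted p = 0.00170), within a range over 18 alternatives from 4.95e-05 by fry to 0.382 with an estimated correlation. STAT3 targets had 2 of 20 higher in the knockout line (median -0.04, mean 0.16, camera direction up, 0.323), then 1 higher and 4 lower in tumour against knockout (0.485) and 4 and 4 against wild-type (0.658), with the receptor Osmr at least 10.9-fold lower in tumour against knockout. The calls in the knockout line, of Osmr and Lif, were lost with the mean of probe sets (0.56 and 0.73). That of Osmr was also lost without wild-type replicate 2 (0.996). ErbB receptors and ligands had 1 higher of 13, Nrg1 (1.78 ± 0.13; median -0.04, mean 0.19, camera direction up, 0.314), then 3 higher and 1 lower in tumour against knockout (median -0.01, mean 0.15, down, 0.898) and 4 higher against wild-type (0.565), with the ligand Hbegf at 2.45 ± 0.21 and 2.41 ± 0.21. Immediate early genes had 1 higher and 1 lower of 14 in the knockout line (median -0.11, mean -0.03, camera direction up, 0.849), 2 and 2 in tumour against knockout (0.493) and 2 and 4 against wild-type (0.476).

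Matrix proteases and their inhibitors had 2 higher and 2 lower of 21 in the knockout line (adjusted p = 0.645) and 4 and 4 in both comparisons of the tumour line (0.640 and 0.771), with the collagenase Mmp13 at least 9.58-fold higher and Adamts1 at -3.61 ± 0.09 in tumour against knockout. Genes of MHC class I presentation had 0 of 15 called in the knockout line (0.220), 2 lower in tumour against knockout (0.597) and 2 higher and 3 lower against wild-type (0.135), with the peptide-loading chaperone Tapbp at -1.91 ± 0.11 and -2.16 ± 0.11. With the mean of probe sets both higher calls, H2-D1 (0.69) and H2-K1 (0.44), were lost. So was Tap1, lower against knockout (-0.36) and wild-type (-0.24). Tap2 against wild-type was lost without wild-type replicate 1 (-0.99). Stress genes of unfolded proteins had 0 of 20 called in the knockout line (median 0.0057, mean -0.02, camera direction up, 0.869), 3 higher and 1 lower in tumour against knockout (0.136) and 3 higher against wild-type (0.139), with the kinase-like Trib3 at 1.76 ± 0.15 and 1.28 ± 0.15. Cholesterol synthesis had 1 lower of 19 in the knockout line, Pmvk (-1.05 ± 0.11; list 0.10), whose call was lost under quantile normalization (-0.97) and without wild-type replicate 2 (-1.0), 0 in tumour against knockout (0.405) and 1 lower against wild-type, Dhcr7 (-1.07 ± 0.09; median 0.08, mean -0.08, camera direction down, 0.839). Oncofetal and imprinted genes had 3 lower of 15 in the knockout line (0.306), among them Peg3 at -4.64 ± 0.26. Cdkn1c was another, and its call was lost without wild-type replicate 1 (-0.94) and without knockout replicate 1 (-0.90). In tumour against knockout 1 was higher, Hmga2 (2.14 ± 0.11; median -0.06, mean 0.14, camera direction up, 0.849), and against wild-type 2 were higher and 3 lower (0.425).

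Genes whose symbols share a stem were tested for calls on 1 side with Fisher's exact test in 324 families of at least 8 genes, and 17 of the 1944 tests passed an adjusted p of 0.05. Members of a family lie close together or move together and can cross-hybridise, so these p-values treat dependent genes as independent. In the knockout line 10 of 15 Lce genes, of the cornified envelope, were lower (adjusted p = 2.64e-09), with Lce3a at -5.25 and Lce1d at -3.43, and 9 of 48 keratin genes were lower and 1 higher (0.00226), with Krt19 at -4.90 and Krt1 at -4.18. Sprr genes, also of the cornified envelope, were lower in 5 of 9 in knockout against wild-type (0.000737), 6 in tumour against knockout (0.00115) and 8 in tumour against wild-type (2.10e-05), with Sprr1b at least 37-fold lower in the last. In the tumour against the knockout line 8 of 10 Mcm genes, of the replicative helicase and its relatives, were higher (2.52e-05), with Mcm6 at 2.67. The genes named in this paragraph were chosen after their values were seen.

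Calls were counted in other splits of the arrays. The 6 arrays of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. For called genes 1 of 10 splits, the real one, reached the real number in each comparison: 888, 2578 and 3012, against a highest other of 0. Every other split mixes the lines and carries their difference in its residual spread, so these 0 calls decide nothing. For lists past the threshold, adjusted within the comparison, the real splits gave 6, 4 and 6 and the highest others 5, 6 and 4; 1, 4 and 1 of the 10 splits reached the real number. Of 100 drawn regroupings of the 9 arrays, 3 gave as many shared calls as the real 529, with a highest other of 2216, and 2 gave as many stepwise calls as the real 151, with a highest other of 151. These shares exclude only that the arrays fell into 3 lines by chance: regroupings that mix the lines carry the line differences in their residual spread and gave 0 stepwise calls, so whether the overlaps exceed chance is not tested by them. The 2 other regroupings that reached 529 had the tumour arrays as the shared control, 1977 in the regrouping that keeps the 3 lines whole and 2216 in one that mixes the wild-type and knockout arrays; such counts point to the structure of the samples, the distance of the tumour arrays from the rest.

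The rise of p53 targets in the knockout line (median 0.78, 10 of 22 higher, on 15 chromosomes for the list) was weighed against 2 technical explanations. If the poor 3' to 5' difference of wild-type replicate 3 were the cause, the rise would shrink without that array, but the median was then 0.81. If shifts of whole chromosomes were the cause, subtracting each chromosome's median would lower it, but the median was then 0.84. The highest chromosome median was 0.28, for chromosome 19, so the subtraction could not have removed a rise of 0.78. It shows only that median shifts of this size are too small for the rise. In other splits of the 6 arrays the largest median of this list was 0.36. Those splits put arrays of both lines on each side, which shrinks any line difference, so this smaller median is no support. What stays open is the line itself: with 1 line per genotype, a difference in culture or passage may give the same rise as the loss of Gprc5a, and over the alternatives the list's adjusted p ranged from 8.41e-10 without wild-type replicate 1 to 0.0628 with an estimated correlation.

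Y-linked transcripts were highest in the wild-type line and Xist in the tumour line. In the knockout line the brightest probe set of Eif2s3y and 1 of the 3 Kdm5d probe sets were at background. A second Uty probe set read 5.42 there, between 7.87 in the wild-type and 3.26 in the tumour line. That value lay under the highest bacterial control value, 5.96, and was not assigned to transcript or background. If arrays of the wild-type and knockout lines had been swapped, at least 1 array would lie on the other line's side for Eif2s3y or Gprc5a, but 0 arrays did; since Eif2s3y prompted the question, this rests on Gprc5a, at 8.32 to 8.74 on the wild-type and 7.09 to 7.20 on the knockout arrays. If sex-chromosome genes made up much of the difference between these lines, they would hold a large share of its calls, but 27 of 888 called genes (3.04%) lie on X or Y against 626 of all genes tested (3.44%; Fisher's exact p = 0.571), 2 of them on Y. A candidate explanation is a difference in the sex of the donor mice or a loss of the Y chromosome or of Xist in culture; the labels give the sex of the tumour's mouse only, and this was not tested.

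Median differences of whole chromosomes were far from 0 among the 9826 genes with a mean log2 signal above 7: -0.33 for chromosome 4, 0.28 for 19 and -0.28 for 8 in knockout against wild-type, 0.40 for chromosome 16, -0.38 for 8 and 0.31 for 4 in tumour against knockout, and -0.64 for chromosome 8, 0.27 for 16 and 0.21 for 6 in tumour against wild-type. With each of these chromosomes split into 4 segments, 12 of 12 segments had medians on the chromosome's side in the first comparison, 12 of 12 in the second and 12 of 12 in the last, but chromosomes picked for their largest medians over so many genes would mostly do so, and this decides little about neighbouring genes; in the knockout against the wild-type line the segment median farthest from 0 was 0.64 in the first segment of chromosome 3, whose median as a whole was -0.0021, so shifts were not always of whole chromosomes. A permutation test that shuffles genes between chromosomes gave p = 0.0001 in each, the smallest it can give here, but it ignores the dependence of neighbouring genes. A permutation test by circular shifts of the gene order, which keeps it, gave p = 0.369 for knockout against wild-type and p = 0.200 for tumour against wild-type, where it found 2 and 4 of 20 planted shifts and decides nothing, and p = 0.154 for tumour against knockout, where it found 19 of 20. A chance arrangement of co-regulated genes is therefore not excluded in any comparison, and gains or losses of chromosomes in culture may be a source only as an untested hypothesis.

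The region of Gprc5a held no excess of calls: of the 30 tested genes on each side, 3 of 60 were called in knockout against wild-type, Rerg (at least 1.65-fold lower), Eps8 at 1.15 and Mgst1 at 1.93, which is 5.0% against 4.88% of all genes (Fisher's exact p = 0.768). The call of Mgst1 was lost with the mean of its probe sets (0.98).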
